A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

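The series measured newly made RNA in a budding yeast (Saccharomyces cerevisiae) strain whose Ssl2 protein carries an FRB tag. Ssl2 is a DNA translocase of TFIIH, a general transcription factor of RNA polymerase II. In the anchor-away method, rapamycin binds the FRB tag to an anchor protein that leaves the nucleus, which removes the tagged protein from the nucleus. Per the labels' protocols, cells were grown at 30 C in rich medium from an OD600 of 0.1 to 0.8, labelled with 5 mM 4-thiouracil for 6 min and frozen, spike-ins were added before lysis, labelled RNA was purified from total RNA, and libraries were made with the NuGEN Ovation Universal kit from 100 ng of RNA. The rapamycin dose and the time of exposure were not given in the labels. There were 2 libraries without rapamycin and 2 with it, and the group and replicate number of each came from its title and group label. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

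The authors deposited raw read counts for 6030 annotated transcripts in each library, together with the transcript annotation. Per the submitters' processing notes, the tools were STAR 2.3.0, SAMtools and HTSeq, and the builds sacCer3 and R64. The notes give these tools no role or order. The alignment filters and the strand setting of the counting were not given in the sources used here. The annotation held 4928 open reading frame transcripts, 500 stable unannotated transcripts (SUTs), 433 Xrn1-sensitive transcripts (XUTs) and 169 cryptic unstable transcripts (CUTs), the last 3 classes being noncoding. By systematic name, 4842 features matched the reference gene table of R64, and all 4842 open reading frames lay inside their deposited transcript on the same chromosome, so positions are given as in the deposited annotation on R64. Of 213 features lying wholly under a feature of the opposite strand, 194 had counts in every library, with a median of 70 in no rapa replicate 1, so the counting kept the strands apart. The deposited annotation covered 70.0% of the 1336 reference genes over 2000 bp and 83.4% of the 4685 shorter ones. SSL2 was not analysed here, and neither were spike-ins or transcripts of RNA polymerases I and III.

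Counts on features summed to 32435994 and 29318499 without rapamycin and to 11441998 and 12685769 with it. The rows that name no feature were left out of library sizes and tests. Reads outside every feature made up 33.7% and 33.1% of reads without rapamycin and 50.5% and 50.0% with it, and ambiguous reads at most 0.0930%. The row for reads aligned to several places held 0 in every library, so the share of reads that paralogs could have exchanged is unknown, and duplicated genes such as the ribosomal protein pairs are uncertain in that respect. Replicates were first compared for identity: the chi-square per degree of freedom between replicates was 80.4 without rapamycin and 65.7 with it, so no library was a copy of another.

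Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, default filterByExpr, quasi-likelihood F-test of the group term, two-sided), with Benjamini-Hochberg adjustment over the 5707 features that passed the filter and a threshold of 0.05. TMM factors were 0.928, 1.00, 0.966 and 1.11. TMM centres the fold changes on the bulk of genes, so every change is relative to that bulk, and a change shared by most genes is not seen. Levels are CPM with TMM scaling. The SE given with a fold change was derived from the test, as the absolute log2 fold change divided by the square root of its F statistic. The common biological coefficient of variation was 19.8%. On counts simulated from these libraries for the comparison of rapamycin with no rapamycin over 5707 genes, 62% of 100 genes changed by a log2 fold of 1 and 91% of 100 changed by a log2 fold of 2 were recovered, with 9 false calls (5.56% of calls). Only these genes were changed, as many up as down, whereas 2623 features were called in the data. The rates need not hold where so many genes change.

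Gene lists were tested with camera (limma 3.58.1, inter-gene correlation 0.01, log2 CPM with a prior count of 2), with Benjamini-Hochberg adjustment over the 29 lists that had at least 5 tested members. An estimated correlation and fry were run beside it. The result of 1 of the lists is not reported here. With 2 residual degrees of freedom, no list passed with an estimated correlation, and every adjusted p was at least 0.738. The lists were fixed before the data were examined, as were the main tests and the rule for named genes. That rule took every TFIIH subunit, the 10 genes with the highest and the 10 with the lowest log2 fold change among those past the threshold with a mean log2 CPM of at least 5, a standard symbol and no overlap between groups, and up to 4 called members of each list with the smallest adjusted p.

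Core promoter sequence was read from the R64 genome relative to the annotated transcript start. A TATA element was TATAWAWR on the sense strand within 200 bp upstream. GC content was taken in 4 windows of 50 bp that start at -150, -100, -50 and 1. Medians and Spearman correlations across genes were tested by permutation with 100000 resamples, two-sided, or 10000 resamples within bins for matched comparisons. Such tests treat genes as independent, which they are not. Alternatives covered the scaling (median-of-ratios factors, total library size), the filter (none, or at least 10 CPM in at least 2 libraries), the test (DESeq2 1.42.0, limma-voom), the replicate number as a block, a 2-fold minimum, and leaving out each library. A fit without 1 library has 1 residual degree of freedom, and its spread comes only from the group that keeps both libraries. Thinning all libraries to the depth of the shallowest and the use of open reading frames alone were added after the data were seen, as was the comparison of transcript classes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the remaining steps.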

Results

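Labelled RNA was compared between 2 libraries of the Ssl2 anchor-away strain without rapamycin and 2 libraries of the same strain with rapamycin. The comparison addressed how transcription changes when Ssl2, the TFIIH subunit that drives promoter opening, is moved out of the nucleus. Feature counts were 32435994 and 29318499 without rapamycin and 11441998 and 12685769 with it. Log2 CPM correlated at Pearson's r = 0.992 between the replicates without rapamycin, 0.968 between those with it, and 0.920 to 0.923 between groups, across genes, which are not independent.

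With rapamycin, most tested genes for cytosolic ribosomal proteins took a larger share of the labelled RNA, while most of those for chaperones, stress proteins, mitotic regulators, iron uptake and short-lived regulators took a smaller one. None of these lists passed when camera used an estimated correlation (adjusted p = 0.738 for each). With fry, the ribosomal protein (adjusted p = 0.0398), G2/M (0.0398) and short-lived (0.0403) lists passed. The chaperone (0.0664), iron (0.0664) and Msn2 and Msn4 stress (0.115) lists did not pass with fry. Without overlapping transcripts, the camera calls of the stress and short-lived lists were also lost (adjusted p of 0.105 and 0.104). That left 19 of 26 and 5 of 15 genes, with medians of -0.61 and -0.80 against -0.72 and -0.87 on the log2 CPM scale of camera. Among called genes with a standard symbol and a mean log2 CPM of at least 5, the highest change was that of RPL41B, which encodes a large-subunit ribosomal protein and rose 10.5-fold, though its rank rested on with rapa replicate 2. The lowest was that of ARO10, a phenylpyruvate decarboxylase gene, which was 12.5-fold lower. Of 5707 features tested, 2623 changed, with 1101 higher and 1522 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 3046 had an unadjusted p under 0.05. Of the called features at any level, 278 were at least 4-fold higher and 109 at least 4-fold lower. At any fold change, more of the called features were lower than higher. Among those with a standard symbol, a mean log2 CPM of at least 5 and no overlap between groups, 626 were higher and 1283 lower. Both libraries with rapamycin lay on the same side of both without it for 4235 features, or 74.2%, where chance gives 33.3%. Leaving out 1 library without rapamycin lowered the count of changed features to 1588 (without replicate 1) or 1685 (without replicate 2), and the higher calls to 532 or 531. Leaving out 1 library with rapamycin raised the count to 3312 or 2934. Each such fit has a single library in its smaller group and takes its spread from the other group's pair alone, so counts and list calls from these fits partly reflect which pair supplies the spread.

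The 10 genes with the highest fold change included 6 for ribosomal proteins. RPL41B (YDL133C-A, chromosome IV, 221523 to 221819, R64) rose from 41.1 ± 10.9 to 432 ± 213 CPM (SD, n = 2), a log2 fold change of 3.39 ± 0.32 (SE) with an adjusted p of 1.06e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without with rapa replicate 2 its log2 fold change was 2.87, below those of RPS25A (3.05) and RPL41A (2.94). Its near-identical copy RPL41A (YDL184C, IV, 130197 to 130506) rose from 64.6 ± 4.12 to 453 ± 17.1 CPM, and the 2 can exchange reads. RPS25A rose by a log2 fold change of 2.83 ± 0.23, RPS17A by 2.55 ± 0.26, RPP1A by 2.45 ± 0.30 and RPP2B by 2.21 ± 0.21. The other 4 were MRX10, a mitochondrial protein gene (IV, 1023319 to 1024762; 2.39 ± 0.18), SHC1, which encodes a sporulation-specific activator of a chitin synthase (2.37 ± 0.28), TPM1, the major tropomyosin (2.35 ± 0.20), and GFD2 (2.29 ± 0.20). TPM1 rose from 162 ± 3.79 to 828 ± 87.2 CPM (SD, n = 2).

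The 10 genes with the lowest fold change were led by ARO10 and HSP30. ARO10 (YDR380W, IV, 1234113 to 1236253) fell from 615 ± 160 to 49.1 ± 6.90 CPM (SD, n = 2), a log2 fold change of -3.65 ± 0.24 (SE; adjusted p = 2.21e-06, edgeR quasi-likelihood test, Benjamini-Hochberg). HSP30, which encodes a stress-induced plasma membrane protein, fell from 1413 ± 262 to 118 ± 18.5 CPM (-3.58 ± 0.25). Lower by the same test were TMA10 (-3.37 ± 0.23), the NADPH dehydrogenase gene OYE3 (-3.36 ± 0.22), the glutathione peroxidase gene GPX2 (-3.04 ± 0.18), SFK1 (-2.93 ± 0.18), the drug transporter genes FLR1 (-2.92 ± 0.34) and ATR1 (-2.86 ± 0.24), the trehalose synthase subunit gene TSL1 (-2.89 ± 0.29) and FRM2 (-2.88 ± 0.20). FLR1 went from 3752 ± 103 to 495 ± 203 CPM.

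**Figure D1:**
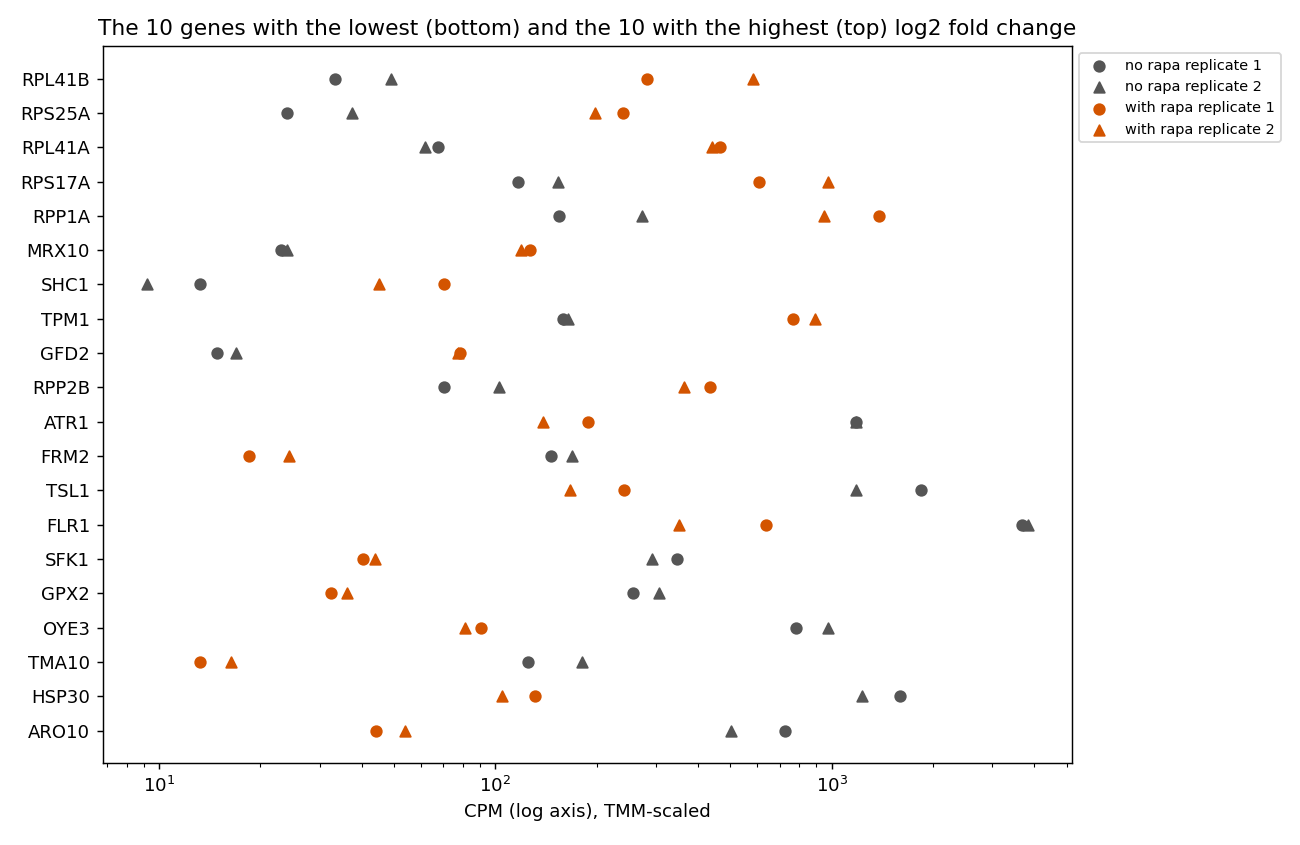
Level of each of the 20 genes named by fold change in the 4 libraries, in TMM-scaled CPM on a log axis, with grey markers for libraries without rapamycin, orange for those with it, and 1 marker per library. The genes were chosen among those whose orange and grey markers do not overlap, such as RPL41B (41.1 against 432 CPM as means) and ARO10 (615 against 49.1 CPM).

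Most ribosomal protein genes were higher, while many genes of ribosome assembly and of amino acid synthesis were uncalled. Of 134 cytosolic ribosomal protein genes, 118 were higher, 0 lower and 16 uncalled (also 118 and 0 adjusted over the list alone), with a median log2 fold change of 1.39, or 2.62-fold. RPS24A rose from 129 ± 1.82 to 525 ± 50.2 CPM and RPL23A from 97.8 ± 1.90 to 384 ± 56.1 CPM (SD, n = 2). Of 97 ribosome biogenesis genes, 34 were higher, 4 lower and 59 uncalled (33 and 4 adjusted over the list alone), with a median of 0.33. Its higher members included LTV1 (1.34 ± 0.18), FPR3 (1.62 ± 0.24) and the RNA helicase gene DRS1 (1.22 ± 0.21). Of 40 amino acid synthesis genes under Gcn4, the activator of that pathway, 20 were higher, 3 lower and 17 uncalled (21 and 4 adjusted over the list alone; median 0.51). ILV6 (1.57 ± 0.23), HOM2 (1.54 ± 0.20) and ARG4 (1.27 ± 0.18) rose, and CPA1 fell (-1.32 ± 0.17). The camera test of limma gave an adjusted p over 29 lists of 4.84e-23 for ribosomal proteins, 0.00207 for ribosome biogenesis and 0.00873 for the Gcn4 list. Each had an adjusted p = 0.738 with an estimated correlation. The Gcn4 call was lost without no rapa replicate 2 (adjusted p = 0.0749, camera) and without with rapa replicate 1 (0.0960), with log2 CPM medians of 0.33 and 0.43 against 0.52 with all libraries.

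Most chaperone genes were lower, with a smaller shift of stress genes. Of 27 chaperone genes under Hsf1, the heat shock factor, 0 were higher, 20 lower and 7 uncalled (also 20 adjusted over the list alone), with a median log2 fold change of -1.61 (camera adjusted p = 3.01e-06). BTN2 went from 5551 ± 699 to 883 ± 184 CPM and HSP42, a small heat shock protein gene, from 3585 ± 822 to 537 ± 135 CPM (SD, n = 2). CUR1 (-2.20 ± 0.21) and the mitochondrial co-chaperone gene MDJ1 (-1.78 ± 0.21) also fell. The chaperone transcripts had a median length of 1847 bp and a median log2 CPM of 11.1, against 1431 bp and 6.25 for open reading frames. Across genes, fold change fell with length and with level. The chaperone list was not compared with genes matched on either, so its shift was not separated from those trends. Of 26 stress targets of Msn2 and Msn4, 2 were higher, 15 lower and 9 uncalled (2 and 15 adjusted over the list alone; median -0.67, camera adjusted p = 0.0257), among them YGP1 (-2.06 ± 0.16), GRE3 (-1.64 ± 0.18) and the trehalose phosphatase gene TPS2 (-1.92 ± 0.26). With an estimated correlation both lists had an adjusted p = 0.738. The camera call of the Msn2 and Msn4 list was lost without no rapa replicate 1 (adjusted p = 0.0736), without with rapa replicate 2 (0.0849) and without transcripts that overlap another (0.105), with log2 CPM medians of -0.62, -0.40 and -0.61 against -0.72.

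Most tested genes of mitosis were lower. Of 14 G2/M genes, 0 were higher, 11 lower and 3 uncalled (also 11 adjusted over the list alone; median -1.19, camera adjusted p = 0.00617), including the cyclin gene CLB2 (-1.32 ± 0.16) and the regulator genes SWI5 (-1.30 ± 0.16) and NDD1 (-1.34 ± 0.17). CLB2 went from 172 ± 0.507 to 68.8 ± 0.844 CPM (SD, n = 2). The list had an adjusted p = 0.738 with an estimated correlation. Of 30 genes of G1/S and DNA replication, 7 were higher, 3 lower and 20 uncalled (6 and 2 adjusted over the list alone; median 0.23, camera adjusted p = 0.0598), with CDC21 (1.28 ± 0.20) and SMC3 (0.96 ± 0.17) higher and HCM1 (-1.82 ± 0.19) lower. That list passed the threshold as higher without with rapa replicate 2 (adjusted p = 0.0414, camera) and with open reading frames alone (0.00908). Of 11 histone genes, 1 was higher (HTA2, 0.65 ± 0.22), 3 were lower (HTZ1, HTB2 and HHT2) and 7 uncalled (1 and 3 adjusted over the list alone; camera adjusted p = 0.471).

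Most tested short-lived regulator mRNAs, iron regulon genes and methionine genes were lower. Of 15 short-lived mRNAs of regulators, 1 was higher, 12 lower and 2 uncalled (1 and 12 adjusted over the list alone; median -0.87, camera adjusted p = 0.00502), with the glycolytic activator gene TYE7 (-1.78 ± 0.17), the repressor gene MIG3 (-1.92 ± 0.21) and the proteasome regulator gene RPN4 (-1.53 ± 0.28) among those lower. Of 24 iron regulon genes, 1 was higher, 16 lower and 7 uncalled (1 and 16 adjusted over the list alone; median -1.03, camera adjusted p = 0.00107), and the ferric reductase gene FRE1 went from 1483 ± 20.5 to 299 ± 34.5 CPM (SD, n = 2). Of 19 methionine and sulfate genes, 0 were higher, 12 lower and 7 uncalled (also 12 adjusted over the list alone; median -0.60, camera adjusted p = 0.0199), including the permease genes MUP1 (-2.44 ± 0.32) and MMP1 (-1.90 ± 0.24). With an estimated correlation all 3 lists had an adjusted p = 0.738. Without with rapa replicate 2, the log2 CPM median of methionine genes was -0.49, against -0.63 with all libraries. The camera call was lost without overlapping transcripts for methionine genes (adjusted p = 0.0515) and for the short-lived mRNAs (0.104). Without overlapping transcripts, 10 of 19 methionine genes were left and their log2 CPM median was the same at -0.63.

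Rapamycin also inhibits the TORC1 kinase in strains that are sensitive to it, and the labels do not state the sensitivity of this strain. Of 23 nitrogen catabolite repression targets, which rise when TORC1 is inhibited, 3 were higher, 12 lower and 8 uncalled (4 and 12 adjusted over the list alone; median -0.57, camera adjusted p = 0.0781), with PUT1 (-2.36 ± 0.23), DAL7 (-1.40 ± 0.18) and DUR3 (-1.30 ± 0.17) lower. The log2 CPM median of that list was -0.50 and -0.64 without no rapa replicate 1 or 2, and -0.66 and -0.28 without with rapa replicate 1 or 2. Without overlapping transcripts it was -0.41 (camera adjusted p = 0.323). Of 8 retrograde response targets, 1 was higher, 2 lower and 5 uncalled (2 and 5 adjusted over the list alone; camera adjusted p = 0.471). Of 22 subunits of RNA polymerases I and III, 5 were higher, 0 lower and 17 uncalled (also 5 adjusted over the list alone; camera adjusted p = 0.118). The polymerase list passed with open reading frames alone (adjusted p = 0.0237, camera).

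**Figure D2:**
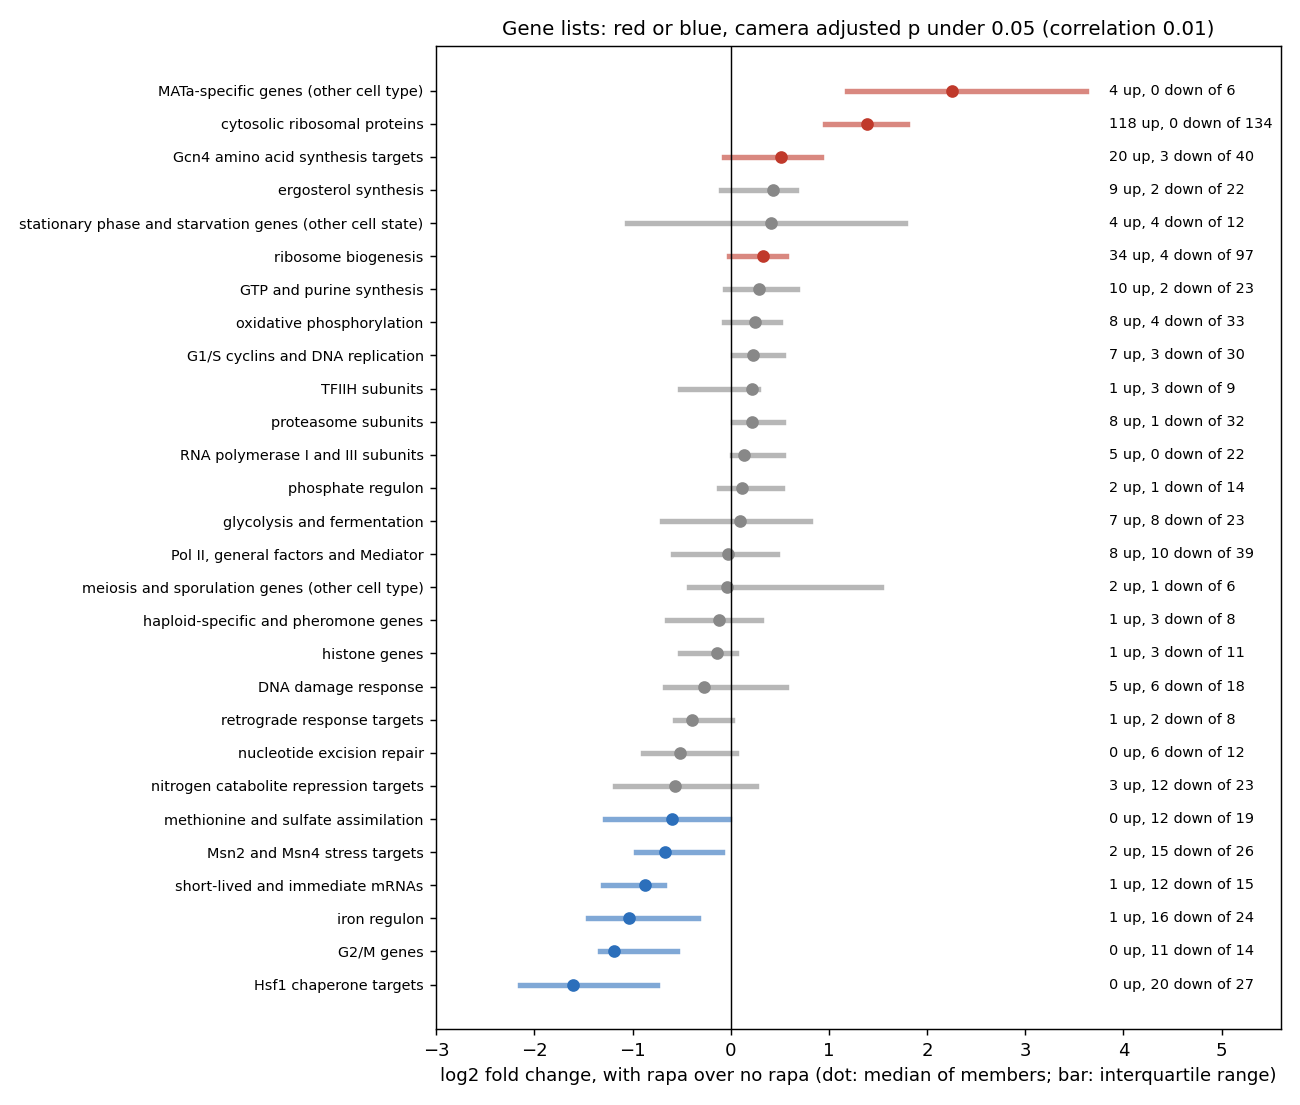
Median (dot) and interquartile range (bar) of the log2 fold change of the members of each reported list with at least 5 tested genes, with rapamycin over no rapamycin. Red and blue mark camera adjusted p under 0.05 for higher and lower lists, grey the rest, and the right-hand text counts the called members, such as 118 up and 0 down of 134 ribosomal protein genes.

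Genes of glycolysis and fermentation went both ways. Of 23 genes of glycolysis and fermentation, 7 were higher, 8 lower and 8 uncalled (7 and 8 adjusted over the list alone; camera adjusted p = 0.916), and the median (0.10) and mean (-0.11) differed in sign. The log2 CPM median was 0.06 with all libraries. It was 0.33 and -0.15 without no rapa replicate 1 or 2, and -0.24 and 0.42 without with rapa replicate 1 or 2. Lower were the hexose transporter genes HXT1, from 1488 ± 15.2 to 219 ± 59.1 CPM (SD, n = 2), and HXT3 (-1.98 ± 0.25), and TDH1 (-2.46 ± 0.19). Of 22 ergosterol genes, 9 were higher, 2 lower and 11 uncalled (11 and 2 adjusted over the list alone; camera adjusted p = 0.0588), with ERG20 (1.20 ± 0.19) and ERG2 (1.16 ± 0.16) higher and HMG2 (-1.39 ± 0.17) lower. Of 23 purine and pyrimidine synthesis genes, 10 were higher, 2 lower and 11 uncalled (10 and 2 adjusted over the list alone; camera adjusted p = 0.0601), with GUA1 at 1.37 ± 0.24. Of 33 oxidative phosphorylation genes, 8 were higher, 4 lower and 21 uncalled (7 and 4 adjusted over the list alone; camera adjusted p = 0.159), with COX5A higher (1.05 ± 0.19) and NDI1 lower (-1.27 ± 0.17). Of 32 proteasome genes, 8 were higher, 1 lower (RPN4, their activator) and 23 uncalled (7 and 1 adjusted over the list alone; camera adjusted p = 0.0598). Of 14 phosphate genes, 2 were higher (PHO86 and PHO8), 1 lower (PHO89) and 11 uncalled (2 and 1 adjusted over the list alone; camera adjusted p = 0.436). With open reading frames alone, camera called higher the lists of ergosterol (adjusted p = 0.0116), purine and pyrimidine synthesis (0.0116), oxidative phosphorylation (0.0365) and proteasome genes (0.00907). The log2 CPM median of ergosterol genes was 0.41 with all libraries. It was 0.52 and 0.26 without no rapa replicate 1 or 2, and 0.41 and 0.51 without with rapa replicate 1 or 2. For purine and pyrimidine genes it was 0.27 with all libraries, and 0.38, 0.35, 0.43 and 0.45 in the same order.

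Genes of the transcription machinery went both ways, while the called genes of nucleotide excision repair were lower. SSL2 was not analysed here, and anchor-away moves the protein without targeting its mRNA, so these values do not test depletion. Of the other 9 TFIIH genes, SSL1 was higher (0.48 ± 0.18, adjusted p = 0.0395), while TFB1 (-0.59 ± 0.16, 0.0104), TFB2 (-0.62 ± 0.20, 0.0242) and CCL1 (-0.51 ± 0.19, 0.0428) were lower by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (also 1 and 3 adjusted over the list alone). TFB1 went from 144 ± 2.70 to 95.4 ± 9.10 CPM (SD, n = 2). The helicase gene RAD3 measured 238 ± 6.58 and 241 ± 18.0 CPM and was uncalled, as were KIN28 (0.22 ± 0.22), TFB3 (0.28 ± 0.20), TFB4 (0.22 ± 0.19) and TFB5 (0.78 ± 0.58), and the list had a camera adjusted p of 0.916. With either of the libraries without rapamycin left out, 0 TFIIH genes were called. Of 39 genes for RNA polymerase II, general factors and Mediator, 8 were higher, 10 lower and 21 uncalled (8 and 10 adjusted over the list alone; camera adjusted p = 0.916), with RPB4 higher (1.12 ± 0.18) and TAF1 (-0.99 ± 0.17) and the Mediator gene SIN4 (-0.98 ± 0.18) lower. Of 12 nucleotide excision repair genes, 0 were higher, 6 lower and 6 uncalled (also 6 adjusted over the list alone; camera adjusted p = 0.141), among them RAD1 (-1.11 ± 0.19) and RAD2 (-0.97 ± 0.16). Of 18 DNA damage response genes, which share RAD2, RAD7, RAD16 and RAD23 with that list, 5 were higher, 6 lower and 7 uncalled (5 and 7 adjusted over the list alone; camera adjusted p = 0.653).

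Lists for other cell types and states were measured in the same fit. Of 6 genes specific to MATa cells, 4 were higher, 0 lower and 2 uncalled (also 4 adjusted over the list alone; median 2.25, camera adjusted p = 0.0316). The list had an adjusted p = 0.738 with an estimated correlation. The log2 CPM median of these genes was 1.90 with all libraries. It was 2.72 without with rapa replicate 1 and 0.95, over 5 genes, without with rapa replicate 2. Their levels were low: ASG7 measured 0.421 ± 0.173 CPM without and 6.49 ± 0.153 CPM with rapamycin, and MFA1, an a-factor gene, 0.387 ± 0.0778 and 2.53 ± 2.04 CPM (SD, n = 2). Of 3 tested genes specific to MATalpha cells, too few for the list test, STE3, the a-factor receptor gene, fell from 334 ± 18.7 to 90.7 ± 0.755 CPM and the other 2 were uncalled. Of 8 haploid and pheromone genes, AGA1 was higher (1.62 ± 0.17), STE5, STE12 and STE4 were lower and 4 were uncalled (1 and 3 adjusted over the list alone; camera adjusted p = 0.824). Of 6 meiosis and sporulation genes, DIT1 and SPS4 were higher, IME2 was lower and 3 were uncalled (2 and 1 adjusted over the list alone; camera adjusted p = 0.603, with a median of -0.04 and a mean of 0.39). Of 12 stationary phase and starvation genes, 4 were higher, 4 lower and 4 uncalled (4 and 4 adjusted over the list alone; camera adjusted p = 0.532). ADH2, a glucose-repressed alcohol dehydrogenase gene, rose from 0.724 ± 0.179 to 25.6 ± 2.37 CPM, and the autophagy kinase gene ATG1 fell from 504 ± 74.6 to 109 ± 31.9 CPM (SD, n = 2).

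Noncoding transcripts had a higher median fold change than open reading frames as a whole. Against tested open reading frames of the same read density, no such rise was seen. Of 797 tested noncoding transcripts, 244 were higher, 37 lower and 516 uncalled, with a median log2 fold change of 1.14, against 857 higher, 1485 lower and 2568 uncalled of 4910 open reading frames, with a median of -0.14. By class, 96 of 364 SUTs, 103 of 332 XUTs and 45 of 101 CUTs were higher, and 27, 10 and 0 were lower, with medians of 0.74, 1.26 and 2.07. The difference of medians from open reading frames was 1.28 for all noncoding transcripts (permutation p = 1e-05, also 1e-05 after Benjamini-Hochberg adjustment over the 4 comparisons and the smallest that 100000 resamples give; genes are not independent). This comparison was chosen after the annotation was seen. Noncoding transcripts held 0.580% ± 0.000598 of feature counts without rapamycin and 0.804% ± 0.130 with it (SD, n = 2), and their median level was 1.66 log2 CPM against 6.25 for open reading frames. Against open reading frames matched on read density without rapamycin, which shares its error with the fold change, the difference was -0.18 (permutation p = 0.0027). Matched on density over all libraries, it was 0.01 (permutation p = 0.950). Weak features of either class may have passed the filter through their counts with rapamycin, so the matched comparisons do not decide whether the classes differ. Without with rapa replicate 2 the unmatched difference was 0.80, and for the 188 noncoding transcripts with at least 10 CPM in at least 2 libraries it was 0.61.

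**Figure D3:**
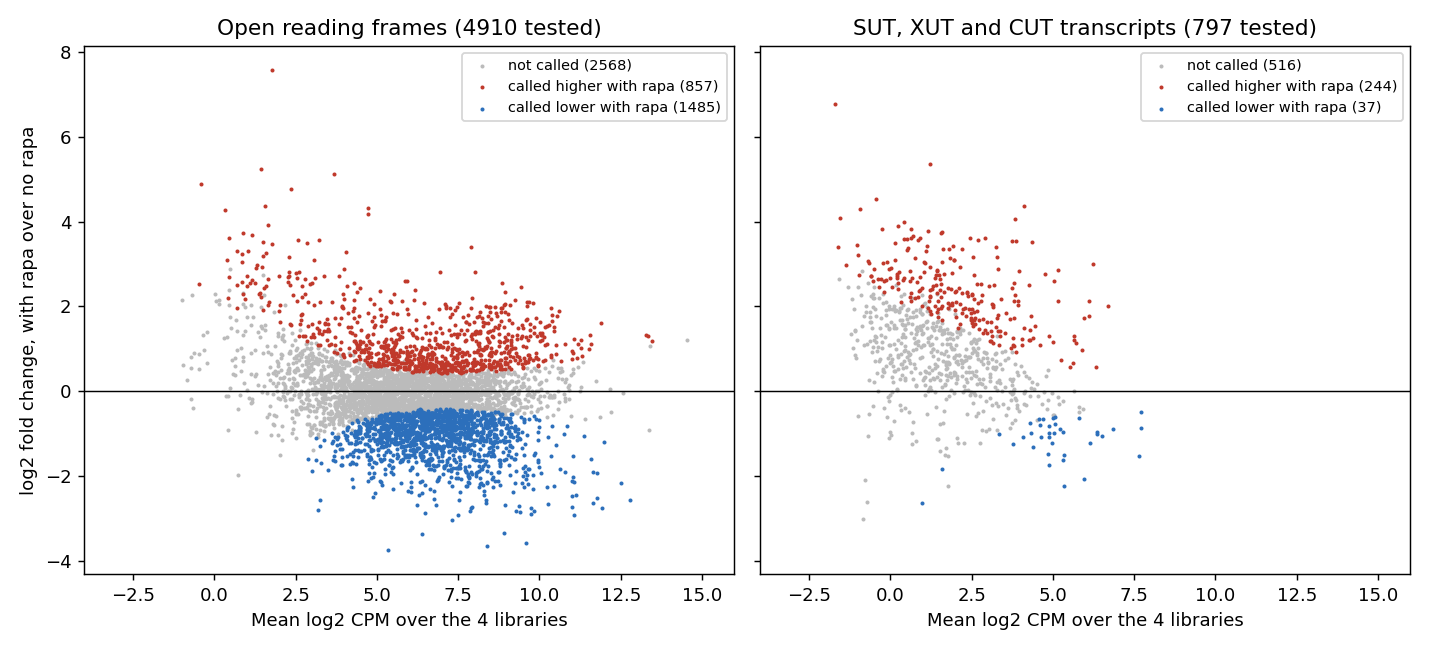
Log2 fold change with rapamycin over no rapamycin (vertical) against the mean log2 CPM over the 4 libraries (horizontal) for 4910 open reading frames (left) and 797 noncoding transcripts (right), with red for called higher, blue for called lower and grey for uncalled. Under a mean log2 CPM of 2, the 158 open reading frames had a median of 1.31 and the 459 noncoding transcripts one of 1.44. At or over it, the 4752 open reading frames had a median of -0.17 and the 338 noncoding transcripts one of 0.72.

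Fold change followed transcript length and starting level across genes. The log2 fold change correlated with transcript length at Spearman's rho = -0.411 and with the level without rapamycin at -0.454 over 5707 features (permutation p = 1e-05 for each, the smallest that 100000 resamples give; a family of 2, with genes not independent). The level shares its error with the fold change. With level and fold change taken from different libraries without rapamycin, rho was -0.417 (permutation p = 1e-05). Without with rapa replicate 2, rho was -0.271 for length and -0.252 for level, and with at least 10 CPM in at least 2 libraries it was -0.266 for level. For open reading frames alone, rho was -0.366 for length and -0.309 for level. Length and level were not adjusted for each other.

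Core promoter sequence was related to the fold change only weakly. The 1279 features with a TATA element within 200 bp upstream of their annotated start had a median log2 fold change of -0.12, against -0.01 for the 4428 without one. The difference was -0.11 (two-sided permutation p = 0.0011, 100000 resamples), and it was -0.14 with genes matched on mean level (permutation p = 1e-04, the smallest that 10000 resamples give). With 1 mismatch allowed in the element, the difference was -0.06 (permutation p = 0.0622). Among features with the element, 17.3% were higher and 31.0% lower, against 19.9% and 25.4% of the others. Of the 4 windows of 50 bp in which GC content was taken, that from -100 to -51 correlated with the fold change at rho = -0.0434 (permutation p = 0.00125, adjusted 0.0050 over the 4 windows). The windows that start at -150 (rho = 0.00276), -50 (-0.00649) and 1 (0.0127) did not pass, with adjusted permutation p of 0.834, 0.832 and 0.672. With level, length and transcript GC held fixed, the window from -100 to -51 gave -0.0628 (adjusted permutation p = 8e-05) and that starting at -50 gave -0.0405 (adjusted permutation p = 0.00446). In 5 equal bins of open reading frames by GC content from -100 to -51, the lowest bin (median 24%) had a median log2 fold change of -0.09 and the highest (median 46%) one of -0.21.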

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

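Reads outside every annotated feature, which no comparison used, made up 50.2% ± 0.352 of reads with rapamycin and 33.4% ± 0.477 without it (SD, n = 2). Only their share was higher: they numbered 11670267 and 12685766 with rapamycin, against 16524704 and 14490965 without it. Feature counts per such read were 1.99 ± 0.0427 without rapamycin and 0.990 ± 0.0138 with it (SD, n = 2). With rapa replicate 2 had 12685769 feature counts and 12685766 reads outside features, nearly the same number for a reason not known, and with rapa replicate 1 alone had 50.5% of its reads outside features. The counts do not record where these reads aligned, and no explanation was tested.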

How the results depend on the processing

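Thinning to 1 depth, the use of open reading frames alone and every check of the noncoding comparison were chosen after the data were seen. Changed genes numbered 1588 to 3312, higher genes 531 to 1535 and lower genes 1056 to 1777 when single libraries were left out. At least 2-fold were 1406 (667 higher, 739 lower). Other counts of changed genes stayed within 1.5 times of 2623. Total library size moved the median of all genes by 0.10 relative to TMM. Higher calls were 42.0% in the main result, 33.5% and 31.5% without no rapa replicate 1 or 2, and at most 47.8% elsewhere. With the replicate number as a block, 2970 genes changed (1250 higher, 1720 lower), 2614 of them shared in direction with the main result. Whether equal numbers mark a shared batch is not stated, and 2 pairs leave it undecided: differences between replicates correlated at Pearson's r = 0.233 (Spearman's rho = 0.191) between groups.

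Of 9 TFIIH genes, 4 were called, against 2 with total library size, the 10 CPM filter, DESeq2 or open reading frames alone, and 0 to 3 with single libraries left out. Past the threshold were 11 lists, against 0 with an estimated correlation, 4 with fry, 7 without overlapping transcripts and 17 with open reading frames alone. With fry, the ribosome biogenesis (adjusted p = 0.0664), methionine (0.0985), Gcn4 (0.195) and MATa (0.0967) lists did not pass. Neither did the chaperone and iron lists (fry adjusted p = 0.0664 for each) or the Msn2 and Msn4 list (0.115). The TATA difference was -0.0637 with 1 mismatch. For GC content in the window starting at -150, rho was -0.0138 with covariates held fixed, -0.00488 with the 10 CPM filter, -0.0246 without ribosomal protein genes, and -0.00390 to 0.0140 with single libraries left out. In that starting at -50 it was -0.0405 with covariates held fixed and 0.0101 without ribosomal protein genes. In that starting at 1 it was -0.0166 with covariates held fixed, -0.00331 with the 10 CPM filter and -0.00973 for open reading frames alone. The noncoding difference was -0.18 with open reading frames matched on density without rapamycin and 0.00537 with density over all libraries. The cause of each change was not tested. Of 288 values of single lists under alternatives, 242 kept their direction and side of the threshold, 27 lost the call and 11 gained it. Of 127 called named genes, 101 stayed called in the same direction in each of the 13 settings that tested them. Calls of named genes were lost 21 times without no rapa replicate 1, 18 times without no rapa replicate 2 and at most 4 times in any other setting, and 0 reversed. Spike-in scaling and the global change of labelled RNA were not run, because spike-ins were not analysed here. With 11441998 counts in the shallowest library, low-count features limit what could be called.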

Other observations

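The tests of the TORC1 and carry-over explanations, and the lists in this first paragraph, were chosen after the data were seen. Most aminoacyl-tRNA synthetase genes were also higher, and a minority of the genes on a translation factor list. Of 19 aminoacyl-tRNA synthetase genes, which charge tRNAs, 14 were higher, 0 lower and 5 uncalled (median log2 fold change 0.79, permutation p against other open reading frames 8e-05, adjusted 0.00024 over 6 lists), such as DED81 (1.30 ± 0.25, SE) and DPS1 (1.33 ± 0.27). Of 31 genes on the translation factor list, 11 were higher, 1 lower and 19 uncalled (median 0.43, adjusted permutation p = 0.00326), with TIF1 at 1.81 ± 0.20 and SUI1 at 1.37 ± 0.19. That list was not limited to translation factors. Its lower gene was TIF6 (-0.44 ± 0.16), also on the ribosome biogenesis list, and GCD10 (0.65 ± 0.16) was counted as higher. Genes for 63 mitochondrial ribosomal proteins split as 2 higher, 6 lower and 55 uncalled, with a median of -0.05 (adjusted permutation p = 0.477). Of 25 genes of the response to oxidants and drugs, a list drawn up after several of its members were seen among the lowest genes and so no independent evidence of its direction, 20 were lower, 2 higher and 3 uncalled (median -1.84). HBN1 (-2.72 ± 0.22) and GRE2 (-2.67 ± 0.27) were among them. Of 32 autophagy genes, 13 were lower and 17 uncalled, and the 2 higher ones, named after their values were seen, were ATG31 (4.19 ± 0.31) and ATG22 (1.95 ± 0.23; adjusted permutation p of the list 0.0874). Of 6 hexose transporter genes, 4 were lower, 1 higher (HXT7) and 1 uncalled (adjusted permutation p = 0.0597).

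Noncoding transcripts had a higher median fold change than open reading frames as a whole. An unequal number of reads as the whole cause is argued against by the thinned libraries, where their median log2 fold change was 1.11. Thinning keeps the expected share of each feature within a library, so it tests nothing beyond the number of reads. The 241 noncoding transcripts with no annotated transcript opposite had a median of 0.88 (interquartile range 0.04 to 1.86). The 556 with one had a median of 1.22. The annotation left out some reference genes, so some of the 241 may lie opposite an omitted gene. Reads from the opposite strand were therefore not excluded as a cause. A background that depends on the level of a transcript stays open. Open reading frames of the same density rose as much: the matched difference was -0.18 with density without rapamycin and 0.01 with density over all libraries. The former density shares its error with the fold change. Weak features of either class may also have passed the filter through their counts with rapamycin, so the matching does not decide the question. Without matching, medians at or over a mean log2 CPM of 2 were 0.72 for noncoding transcripts and -0.17 for open reading frames. The rise may belong to weakly transcribed features in general. Transcription that needs less Ssl2 is a biological alternative that these counts did not separate from such a background.

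Ribosomal protein genes were higher with rapamycin. A bias by transcript length is argued against by the difference of 1.38 from open reading frames of matched length (permutation p = 1e-04, the smallest that 10000 resamples give). Rapamycin acting on TORC1 would be expected to lower ribosomal protein genes and raise nitrogen catabolite repression targets. As the cause of this rise it is argued against by the ribosomal protein median of 1.39, which lay 1.96 above that of those targets. Most of that distance is the rise itself, and the targets alone (median -0.57, camera adjusted p = 0.0781) decide nothing. Abundant long-lived mRNA carried over without label could raise these genes and cannot be told apart, because the 17 enzyme genes of glycolysis and fermentation had a median of 0.10 with an interquartile range of -0.38 to 1.19. The median of the whole list, with its hexose transporters, changed sign when some single libraries were left out. A lower need of these promoters for Ssl2 stays open and was not tested.

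The higher MATa-specific genes may follow the general rise of weakly detected transcripts. Their median of 2.25 lay at the 83.5th percentile of 10000 random lists of open reading frames matched on density without rapamycin, whose central 95% ran from 0.93 to 2.63. Open reading frames at so low a level may have passed the filter through their counts with rapamycin. That would raise the random lists, so the comparison does not decide the question. With 6 genes, most of them near the floor, a contribution of cells of the other mating type was not excluded.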
